A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

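The series measured transcript abundance in budding yeast, Saccharomyces cerevisiae, strain BY4742 (a haploid laboratory strain of mating type alpha, with the genotype given as his3kan in the labels). Cells grew in synthetic complete medium in batch culture, salt was added to 0.7 M NaCl, and total RNA was taken by hot phenol lysis, per the labels' protocols. Labelled cDNA was hybridised to 2-colour NimbleGen arrays that tile the yeast genome. Each of the 2 arrays carried cDNA of salt-stressed cells in channel 1 and of unstressed cells in channel 2. The sample titles place the unstressed cells at the start of the time course. Time in batch culture and salt therefore cannot be told apart within a ratio. The first array held cells 30 min after salt addition and the second held cells 60 min after it. The dyes are the same way round on both arrays, so dye and treatment cannot be told apart. There is 1 array per time, no dye swap and no array of unstressed against unstressed cells. The labels do not say whether the unstressed RNA on both arrays came from the same culture. The names given to the unstressed channel differ between the arrays, and the one on the 30 min array carries a code that is not explained. This bears on each difference between the times.

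The values used are the log2 ratios that the authors deposited, 1 per annotated feature and array. The scanner intensities were not used here, and the aligner, build, background correction, normalization and the way probes were combined into a feature are not given in the sources used here. Both columns of the deposited log2 ratios have a median of 0 over the 6868 features, so they appear to have been centred. The log base is not stated. The values run from -5.16 to 8.32, which as log10 would lie beyond the range of a scanner, and base 2 was assumed. A natural log is not excluded, and every fold would then be larger. The direction of the ratio is not stated either. The sign was kept as deposited. The list of 12 osmostress reporter genes, fixed for this purpose, was used to call a direction likely, as given in the results. Exactly 0 stood in 63 features at 30 min and in 75 at 60 min, 34 of them on both arrays. Of the 104 features listed at 0 on either array, 5 carry a gene symbol. Such a 0 may stand for a missing estimate, and these features were left out of list medians and correlations but kept in the counts over all features.

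Of the 6868 features, 5984 matched a locus tag of the reference gene table (assembly R64), and 5267 of these have a gene symbol that differs from the systematic name. The other 884 features, 582 of them reading frames absent from the table, keep the name in the file. Coordinates are not printed because the build of the array is not given in the sources used here.

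With 1 array per time there are no replicates, so no test against replicate error and no p-value was computed. Genes were described by size, as at least 2-fold from 0 (a log2 ratio of at least 1 or at most -1). The times were compared by the 60 min value minus the 30 min value of each feature. For 37 gene lists, the median log2 ratio over the members was placed among the medians of 10000 random lists of the same size drawn from the 6764 features measured on both arrays. A list was said to stand apart when its percentile was at most 2.5 or at least 97.5. The random lists were not matched on expression, since a table of ratios gives no intensity. The 2 list members left, written as double symbols, matched no symbol in the table. A further set of random lists was matched on the 30 min value, each member being replaced by one of the 100 features nearest to it at 30 min that are not in the list. This second set was added after the data were seen, and was used only where its 30 min median came within 0.1 of that of the list.

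The gene lists, the size threshold, the alternatives other than the one on the log base, and the rule for named genes were fixed before the data were examined. The rule names the 10 highest and 10 lowest features at each time, the 8 highest and 8 lowest differences between the times, the 2 highest and 2 lowest members of each list at 30 min, and every member of the lists of osmostress reporters, glycerol metabolism and BY4742 marker loci. The lists were fixed to cover osmotic stress, metabolism, growth, the cell cycle and cell types or states a haploid culture could hold. Genes outside the rule are said to have been chosen after their values were seen. Not every gene that the rule names is reported here.

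The list procedure was tested on simulated data, made by shuffling the 30 min values over the 6764 features. Of 200 random lists of 20 genes with no planted shift, 5.5% stood apart. These lists were drawn in the same way as the lists they were placed among, so a share near this was set in advance. Shuffling also removes any correlation between co-regulated genes, so the share is not an error rate for the real lists. Other list sizes and the 60 min values were not simulated in this way. With a planted shift of 0.5 (log2) 59.5% stood apart, and with a shift of 1 it was 98.0%. The alternatives were another centring, thresholds of 1.5-fold and 3-fold, the 60 min array rescaled to the spread of the 30 min array, restricted sets of features, the sign turned, means in place of medians, and lists without the member farthest from the median. Spread in the rescaling is the median absolute deviation from the median. The natural log in place of base 2 was added after the data were seen. Leaving out replicates in turn was not possible. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used.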

Results

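Transcript abundance was compared between salt-stressed and unstressed yeast on 2 arrays, 1 for cells 30 min after a shift to 0.7 M NaCl and 1 for cells 60 min after it. The question, as the series title and design state it, is how the transcriptome changes during adaptation to salt. Each value is a log2 ratio of stressed and unstressed cells on the same array, for 6868 features. By the sample titles the unstressed cells were taken at the start, so each ratio also holds the time in culture. There were no replicates, so no value below has an error across cultures, and differences are described by their size only. The spread given beside a list median is the interquartile range over the list's members, which is not a replicate error. The number of arrays, not the depth of any count, limits the precision.

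The direction of the deposited ratio is not stated, and it was taken as likely stressed over unstressed. The basis is that all 12 genes of a list of textbook salt-induced genes had positive values at both times, from 2.01 to 8.32 at 30 min, while 136 of 137 cytosolic ribosomal protein genes were at least 2-fold negative at 30 min. The sample titles name the unstressed cells first, which leaves the direction unsettled. "Higher" and "lower" below follow this likely direction, and all of them swap if the ratio runs the other way. The direction of the reporter and ribosomal protein genes is therefore not a result in its own right. A list of 4 marker loci, deleted in the usual genotype of this strain background, was also fixed beforehand. The genotype was not checked in these data. LEU2 had -2.22 at 30 min and -0.77 at 60 min, URA3 had 1.56 and 0.20, LYS2 had 0.55 and 0.45, and HIS3 had 0.22 at 30 min and was listed at 0 at 60 min. LEU2 (4.66-fold) and URA3 (2.95-fold) thus passed 2-fold at 30 min. If these loci are deleted here, features without a transcript can pass the threshold used for the counts below.

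At 30 min, ratios were far higher for osmotic stress and carbohydrate reserve genes and far lower for the machinery that makes ribosomes. This follows the likely direction, and STL1, GRE1, SIP18, ALD3 and CTT1 below are reporters used for it. The values appear centred, so higher and lower are relative to the other features. The highest value belonged to STL1, the glycerol-proton symporter of the plasma membrane, with 8.32 (320.4-fold). It was followed by TKL2 (transketolase) with 7.36, GRE1 (a hydrophilin) with 7.26, the hexose transporter HXT5 with 7.18, the spore wall gene SPS100 with 7.03, the hydrophilin SIP18 with 6.97, the aldehyde dehydrogenase ALD3 with 6.94, NQM1 (a transaldolase) with 6.85 and the cytosolic catalase CTT1 with 6.40. The reading frame YBR116C, which is absent from the reference table and whose systematic number adjoins that of TKL2 (YBR117C), had 7.25. The lowest value was that of NSR1, a nucleolar protein of ribosome biogenesis, with -5.16 (35.8-fold lower). HO (the mating-type switching endonuclease) had -5.06, AAH1 (adenine deaminase) -5.02, SYO1 (a chaperone of ribosomal proteins) -4.91, RRP12 -4.74, ZEO1 -4.72, UTP23 -4.61, RPA43 (a subunit of RNA polymerase I) -4.60, TRM11 -4.59 and HCA4 -4.57. Of the 6868 features, 1087 were at least 2-fold higher and 1186 at least 2-fold lower, together 33.1%. The SD over features was 1.33.

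Part of the glycerol genes were higher at 30 min. Of 15 genes of glycerol metabolism, 8 were at least 2-fold higher, none was 2-fold lower and 7 were neither (median 1.28, interquartile range 0.57 to 3.49, percentile 100 of random lists). Of these genes 3 (STL1, GPD1 and GPP2) are also among the reporters used for the direction, and of the other 12, 5 were at least 2-fold higher (median 0.78). GPD1 and GPP2, which make glycerol from dihydroxyacetone phosphate, had 3.87 and 4.12. DAK1 (dihydroxyacetone kinase) had 3.68 and GCY1 had 3.30. The glycerol channel gene FPS1 had -0.30 and GPD2, the second glycerol-3-phosphate dehydrogenase, had -0.47. The signalling components of the HOG pathway, which senses osmolarity, were mostly within 2-fold: 20 of 24 were neither, RCK2 had 1.29, SSK22 was among the 3 lower ones and SHO1, an osmosensor, had -1.76 (list median 0.31, percentile 92.1).

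Among cation transport and calcineurin genes, 5 of 24 were at least 2-fold higher and 1 was 2-fold lower (median 0.37, percentile 95.2, not apart from random lists). The sodium pump gene ENA1 had 2.23 and the calcineurin regulator RCN2 had 2.55. ENA1 is also a reporter used for the direction, and of the other 23 genes, 4 were at least 2-fold higher. ENA1, ENA2 and ENA5 are near-identical copies and their values cannot be assigned to single genes with certainty. The one lower gene was PMA1, the plasma membrane proton pump, with -2.10.

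Reserve carbohydrate genes were higher nearly throughout, and redox and chaperone genes in part. In trehalose and glycogen metabolism 18 of 20 genes were at least 2-fold higher (median 2.74, interquartile range 2.18 to 3.73, percentile 100), led by TPS2 (trehalose-phosphate phosphatase) with 4.37 and PGM2 (phosphoglucomutase) with 4.29, while the paralog PGM1 had -0.78. In redox defence 11 of 24 were at least 2-fold higher and GPX2 was lower, with -1.29 (median 0.87). CTT1 of this list is also a reporter used for the direction, and of the other 23 genes, 10 were at least 2-fold higher (median 0.84). GPX1, a glutathione peroxidase, had 3.53. Of 25 chaperone genes, 10 were at least 2-fold higher and 1 was lower (median 0.54, percentile 98.9). SSA4 had 4.30 and HSP26 had 4.28, against -1.29 for YDJ1 and -0.65 for KAR2. All 33 proteasome genes had positive values, but only RPN4, the transcription factor of the proteasome genes, passed 2-fold, with 1.58 (median 0.66, percentile 99.9). Autophagy genes had a median of 1.07 with 20 of 37 at least 2-fold higher, led by ATG39 with 3.51 and ATG8 with 2.61. ATG5 had the lowest value of the list, -0.94, and no member was 2-fold lower.

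The lists of central carbon metabolism differed from each other at 30 min. In the pentose phosphate pathway 5 of 13 genes were at least 2-fold higher and 4 were 2-fold lower, so that the median of 0.19 describes neither. TKL2 had 7.36 against -1.58 for TKL1, and NQM1 had 6.85. RKI1 (ribose-5-phosphate ketol-isomerase) had the lowest value, -3.89. Some further members were chosen after their values were seen. TAL1, the paralog of NQM1, had -0.68. GND2 had 6.14 against -1.32 for GND1, and SOL4 had 4.83 against -0.72 for SOL3. In glycolysis and fermentation 4 of 21 were at least 2-fold higher and 3 were lower (median -0.47, percentile 3.33, mean 0.09). PDC6 had 3.60 and GLK1 (glucokinase) 3.43, while PDC1, the main pyruvate decarboxylase, had -1.36 and TPI1 had -1.16. Hexose transporter genes had a median of 1.42, with 8 of 13 at least 2-fold higher. HXT1 had 2.21 and HXT2 had -1.78. Of 17 tricarboxylic acid cycle genes 7 were at least 2-fold higher, 1 was lower and 9 were neither (median 0.93, percentile 99.9). CIT1 (citrate synthase) had 2.06. For the respiratory chain and ATP synthase, 7 of 32 passed 2-fold upwards and 24 were neither (median 0.36, percentile 96.4, not apart from random lists). RIP1 had 1.77, and CYC1 (cytochrome c) had -2.97. Fatty acid oxidation and peroxisome genes had 11 of 17 past 2-fold, led by POT1 (thiolase) with 4.11 and FOX2 with 3.12, and FAA4 was lower, with -1.38.

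The genes of ribosome production were lower as whole groups at 30 min. Of 90 ribosome biogenesis genes 88 were at least 2-fold lower (median -3.30, which is 9.87-fold, interquartile range -3.80 to -2.69). The exceptions were TIF6 with -0.76 and UTP22 with -0.85. Of 137 cytosolic ribosomal protein genes 136 were at least 2-fold lower (median -2.28, interquartile range -2.54 to -2.10). RPL31B had -3.35, and the exception RPL41B had -0.33. Many ribosomal protein genes are near-identical pairs whose values may be shared. All 19 genes of RNA polymerases I and III (median -2.46), 25 of 33 translation factors (median -1.33) and 12 of 18 tRNA synthetases (median -1.40) were at least 2-fold lower, each at percentile 0 of random lists. YEF3, translation elongation factor 3, had -2.87 and KRS1 had -1.66. The mitochondrial ribosomal proteins did not share this: 66 of 67 were neither 2-fold higher nor lower, with a median of -0.04 (percentile 39.8).

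Biosynthetic and cell cycle genes were lower in part at 30 min. Of 34 amino acid synthesis genes 16 were at least 2-fold lower and none was higher (median -0.80), with LEU9 at -3.38 and LYS4 at -2.66. In purine synthesis 6 of 14 were lower and 3 higher (median -0.24, percentile 21.6). IMD4 and GUA1, of the guanine nucleotide branch, had -3.33 and -2.75, while ADE17 had 1.36. Ergosterol synthesis had 10 of 25 genes past 2-fold downwards (median -0.68), with ERG3 at -2.90 and ERG25 at -2.23. Of the G1/S genes, 14 of 20 were at least 2-fold lower (median -1.44). RNR1 (the large subunit of ribonucleotide reductase) had -3.12, SMC3 (cohesin) -3.01 and the S-phase cyclin CLB6 -2.84. The G2/M list had 8 of 16 past 2-fold downwards (interquartile range -1.35 to -0.66), with the cyclins CLB1 at -2.24 and CLB2 at -1.99. In the M/G1 list only AMN1 passed 2-fold, with -1.01 (median -0.71). Of 10 histone genes 6 were at least 2-fold lower (median -1.11), among them HHF1 with -1.32. In the cell wall list 8 of 21 were lower and 4 higher (median -0.48, percentile 3.09). CIS3 and GAS1 had -2.88 and -2.52, against 5.34 for SPI1 and 3.90 for PIR3.

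Genes of mating type differed from each other. All 5 alpha-specific genes were at least 2-fold lower at 30 min (median -2.06), among them the pheromone genes MF(ALPHA)2 with -3.30 and MF(ALPHA)1 with -2.98. The a-specific genes, which alpha cells do not use, had a median of 0.26 with 1 of 7 past 2-fold (ASG7). Of 17 pheromone response genes 9 were at least 2-fold lower and none was higher (median -1.06). The cell cycle inhibitor FAR1 had -2.99 and the agglutinin subunit AGA1 had -2.29. The phosphate regulon had 6 of 14 genes lower and 1 higher (median -0.87), with PHM6 at -1.96 and PHM8 at 2.17. The iron regulon went both ways (median 0.31, percentile 87.8), from FRE1 with -2.11 to FIT1 with 2.63. The list of meiosis and sporulation genes, a state not expected in a growing haploid culture, had a median of 1.04 with 14 of 26 past 2-fold. REC114 had 2.34 and MEK1 had 2.11, and SPS4 was 2-fold lower, with -1.41. Reading frames absent from the reference table also leaned upwards at 30 min, with 141 of 582 at least 2-fold higher and 31 lower. Whether the meiosis values lie near background was not tested, as no intensity was used. In sulphur amino acid synthesis 7 of 22 genes were lower and 1 was higher (median -0.07, percentile 39.5), with SAM1 at -1.98 and MET28 at 1.29.

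**Figure D1:**
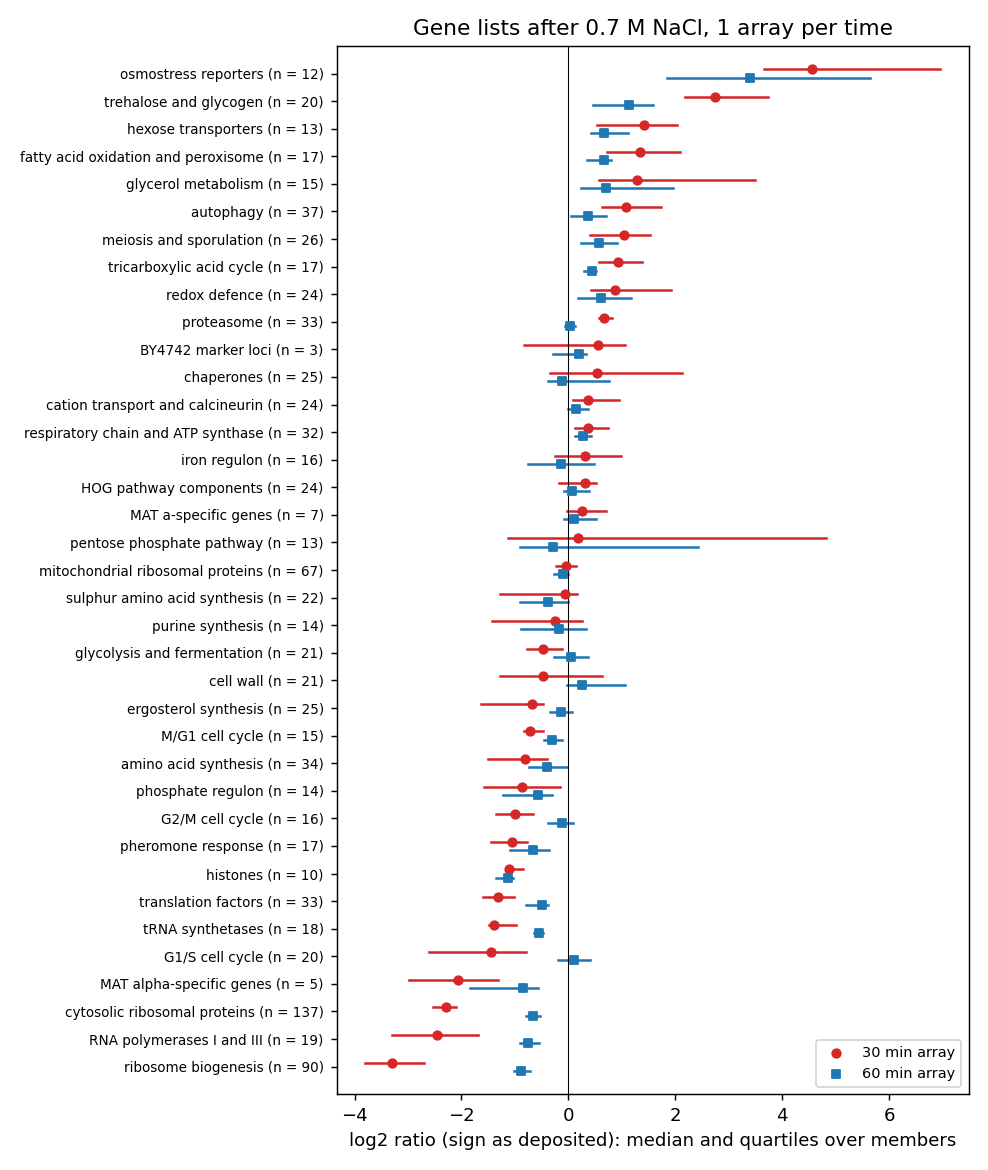
Median log2 ratio (x axis, sign as deposited) of 37 gene lists on the 30 min array (circles) and the 60 min array (squares), with bars for the interquartile range over the members (n, members measured on both arrays). The median of ribosome biogenesis lies at -3.30 at 30 min and at -0.89 at 60 min, while that of histones lies at -1.11 and -1.13.

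At 60 min mostly the same features led, with smaller values, and SAM1, SAM2 and CYS3 of the sulphur amino acid list were among the lowest. GRE1 had 6.53 (92.6-fold), SIP18 6.39, STL1 6.29, NQM1 5.85, SPS100 5.75, TKL2 5.61, YBR116C 5.52, ALD3 5.42, YCL048W-A 5.33 and HBT1 5.26. The lowest were SAM1 (S-adenosylmethionine synthetase) with -3.69 (12.9-fold lower), AAH1 with -2.99, SAM2 (the second S-adenosylmethionine synthetase) with -2.67, YJR071W with -2.64, CYS3 (cystathionine gamma-lyase) with -2.57, the flavohaemoglobin gene YHB1 with -2.48, ZEO1 with -2.46, MF(ALPHA)2 with -2.37, YDL159W-A with -2.29 and the S-adenosylmethionine permease gene SAM3 with -2.28. Of the 6868 features, 458 were at least 2-fold higher and 297 at least 2-fold lower, together 11.0%, and the SD was 0.71. Among these features 60.7% were higher, against 47.8% at 30 min. With the 60 min array rescaled to the spread of the 30 min array, 1155 were higher and 1188 lower, a share of 49.3% higher.

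The osmostress reporters were all positive at 60 min, 11 of 12 past 2-fold (median 3.39, interquartile range 1.84 to 5.64). HSP12 had 3.68 and DDR2 had 3.11, while ENA1 had 0.34. Glycerol genes had 7 of 15 past 2-fold upwards and 1 downwards (median 0.70). GPD1 had 1.29, GPP2 2.72, DAK1 3.37, DAK2 1.95, GCY1 1.97, GUT2 1.09 and GPD2 -1.03. Trehalose and glycogen genes had 11 of 20 past 2-fold upwards (median 1.13), with TPS2 at 1.86 and PGM2 at 1.56, and PGM1 at -1.66. Redox defence had 7 of 24 past 2-fold (median 0.61). Of the chaperones 5 of 25 were at least 2-fold higher, HSP26 with 3.77 and SSA4 with 1.70 among them, while the list median was -0.11 and its mean 0.38. The proteasome list had no member past 2-fold (median 0.03, percentile 63.7).

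The growth genes were still lower at 60 min, mostly by less than 2-fold on the deposited scale. On the rescaled 60 min array the medians were past 2-fold, -1.80 for ribosome biogenesis and -1.35 for ribosomal proteins. All 90 ribosome biogenesis genes and all 137 ribosomal protein genes had negative values, of which 25 and 4 passed 2-fold (medians -0.89 and -0.67, interquartile ranges -1.01 to -0.72 and -0.80 to -0.53). NSR1 had -1.33, RRP12 -1.15, RPA43 -1.12 and YEF3 -1.27. Histones were the list with the lowest median, -1.13, with 8 of 10 past 2-fold. HHF1 had -1.39 and HHT2 -1.02, while HTZ1, the variant H2A.Z, had 0.34 and HHO1, the linker histone, had -0.12. The 8 genes past 2-fold are pairs of copies (HTA1 and HTA2, HTB1 and HTB2, HHT1 and HHT2, HHF1 and HHF2). Their values may be partly shared within a pair. The sulphur amino acid list had 5 of 22 genes past 2-fold downwards and none upwards (median -0.37, percentile 0.13, mean -0.75). Besides SAM1, SAM2 and CYS3, MET6 (methionine synthase) had -1.88, and the fifth, MET17, had -1.97, named here after its value was seen. SAM1 and SAM2 are close paralogs whose values may be partly shared. The cell wall list had 6 of 21 past 2-fold upwards (median 0.25, percentile 98.0), led by PIR3 with 3.62 and SPI1 with 3.13. G1/S genes had no member past 2-fold (median 0.11, percentile 81.9), with RNR1 at 0.73 and CLB6 at 0.78.

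The times were compared feature by feature to describe how the response changed between 30 and 60 min. Values at 60 min were on average closer to 0 and mostly of the same sign. Of the features at least 2-fold from 0 at 30 min and measured on both arrays, 93.0% had the same sign at 60 min. Of the 1087 higher features 355 (32.7%) were still at least 2-fold higher at 60 min, and of the 1186 lower features 243 (20.5%) were still 2-fold lower. With the 60 min array rescaled to the spread of the 30 min array these counts were 700 and 787, so which direction was kept more often depends on the scale of the arrays. Independent lists of these sizes would share 72.5 and 51.3. A further 103 features were 2-fold higher only at 60 min and 54 were 2-fold lower only then. A further 7 features, none with a gene symbol, were 2-fold from 0 with opposite signs. Across the 6764 features measured on both arrays, which are not independent replicates, Pearson's r was 0.79 and Spearman's rho 0.77. Arrays with no effect that share one unstressed reference would give r = 0.50 in simulation. The covariance was 0.76, and at most 0.40 of it could come from a shared reference if the noise of all RNA samples is equal. Part of the overlap may therefore come from the unstressed channel. A dye bias particular to a gene would also add to the covariance, as the dyes are the same way round. The bound does not cover it. The slope of 60 min on 30 min values was 0.46.

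**Figure D2:**
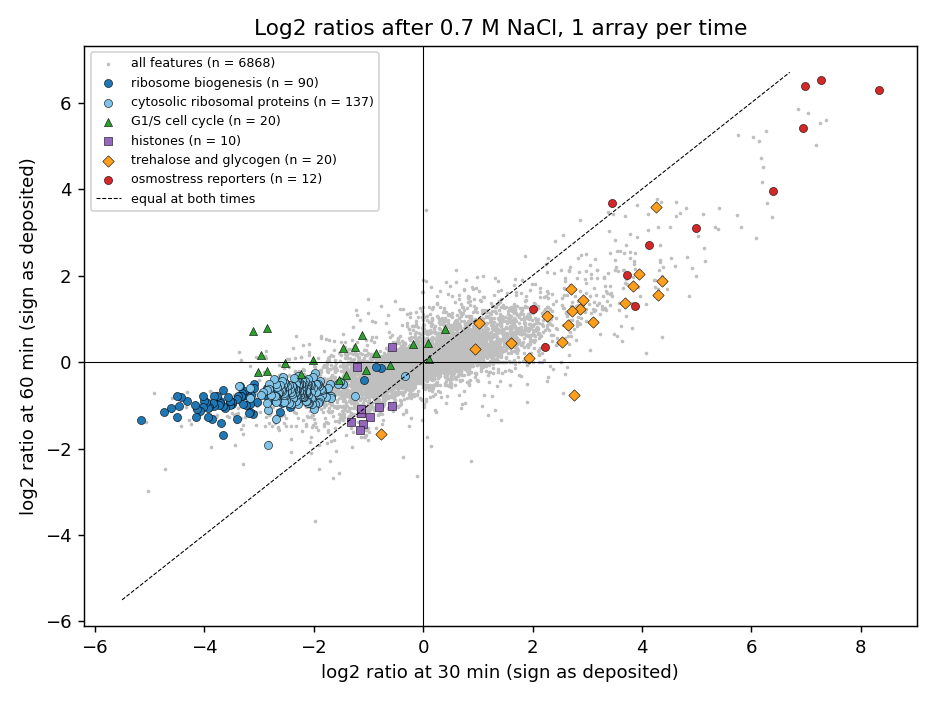
Log2 ratio at 60 min (y axis) against that at 30 min (x axis) for 6868 features (grey) and the members of 6 gene lists (colours), sign as deposited, with a dashed line for equal values. Most ribosome biogenesis genes lie far left and near -0.89 at 60 min, histones lie near the line, and G1/S genes lie around 0.11 at 60 min.

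Between the times, 797 features had a value at least 2-fold higher at 60 min than at 30 min and 608 at least 2-fold lower. The largest upward differences were those of SYO1 (4.19), RNR1 (3.84), NSR1 (3.83), TRM11 (3.76), NOG1 (3.72), HO (3.67), BRX1 (3.63) and CLB6 (3.63). The largest downward differences were those of RGI1 (-3.86, from 4.07 to 0.21), AIM17 (-3.78), the glycogen synthase gene GSY1 (-3.52, from 2.75 to -0.77), GID10 (-3.35), EMI2 (-3.28), SPG4 (-3.22), YDL159W-A (-3.16) and AIM26 (-3.15). By list, 87 of 90 ribosome biogenesis genes and 126 of 137 ribosomal protein genes were at least 2-fold higher at 60 than at 30 min (medians 5.66-fold and 3.07-fold). Trehalose and glycogen genes had 16 of 20 at least 2-fold lower at 60 min than at 30 min (median -1.72), as had 8 of the 12 osmostress reporters (median -1.62) and 12 of 37 autophagy genes (median -0.76). Rescaling the 60 min array to the spread of the 30 min array gave differences of 1.53 for ribosome biogenesis and 0.95 for ribosomal proteins, and of -0.50 for trehalose and glycogen and -0.35 for autophagy. It turned the sign of the median difference for 15 of the 37 lists, the osmostress reporters among them, so the direction of those lists between the times depends on the scale of the arrays.

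Lists with similar values at 30 min differed at 60 min. Random lists matched on the 30 min value came within 0.1 of the list's own 30 min median for 35 of 37 lists. Of these 35, 14 had a 60 min median outside the middle 95% of matched lists, 5 above and 9 below, where 5% would be outside by chance if lists and members were independent. The osmostress reporters and ribosome biogenesis genes could not be matched, as too few features have values as extreme. G1/S genes had 0.11 where matched lists had -0.53 (middle 95% from -0.73 to -0.27). G2/M genes had -0.11 where matched lists had -0.42, and cell wall genes 0.25 where matched lists had -0.10. Lists can lie farther from 0 than matched lists through regression to the mean alone, since features picked for an extreme 30 min value carry more chance error than co-regulated genes do. This limit applies to the following lists. Histones had -1.13 where matched lists had -0.41 (-0.66 to -0.16), and sulphur amino acid genes -0.37 where matched lists had -0.07. If the chance errors of a list's members are independent, this limit does not apply to lists nearer to or past 0. Error shared by the members of a list was not tested. Proteasome genes had 0.03 where matched lists had 0.26, and chaperones -0.11 where matched lists had 0.24. SAM1, SAM2 and CYS3 were each further below 0 at 60 min than at 30 min, by -1.70, -1.02 and -1.03. Cytosolic ribosomal protein genes did not stand apart from matched lists (percentile 93.9).

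**Figure D3:**
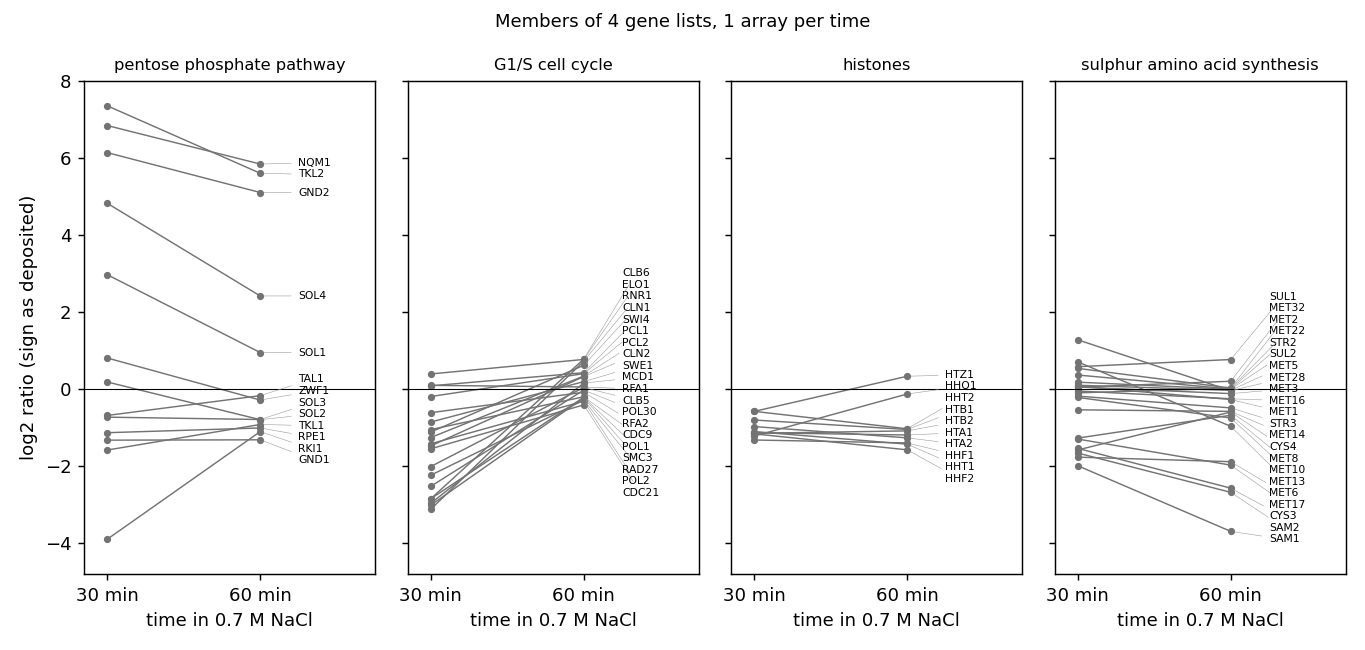
Log2 ratio (y axis, sign as deposited) of each member of 4 gene lists on the 30 min and 60 min arrays, with a line joining each gene's 2 values. RNR1 goes from -3.12 to 0.73, SAM1 from -1.98 to -3.69, and TKL2 stays above 5 while TKL1 stays below 0.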

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

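The tests of explanations in this part were chosen after the results were seen. The means over members and the median without the farthest member are alternatives fixed beforehand. With 1 array per time, none of the differences between 30 and 60 min given here was tested against replicate error. The test of a compression was also revised after its earlier forms had been seen.

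The values below drew attention because the sign at 30 min was opposite to that at 60 min. The median difference (60 min minus 30 min, log2) was 1.67 for G1/S genes, 0.47 for cell wall genes, 0.45 for glycolysis and fermentation, -0.27 for chaperones, -0.28 for the iron regulon and -0.98 for the pentose phosphate pathway. At 60 min the medians were 0.11, 0.25, 0.04, -0.11, -0.14 and -0.28 in the same order. Only that of the cell wall genes stood apart from random lists at 60 min (percentile 98.0). In the G1/S list 19 of 20 members had a positive difference, while the other lists hold more members that went both ways. Values that only move from below 0 towards 0 give such differences too, as in all 137 cytosolic ribosomal protein genes. At 60 min 12 G1/S members lay above 0 and 8 below, and the resampling interval of the median over members, -0.136 to 0.380, includes 0. For the pentose phosphate pathway the mean over members was positive at both times (1.53 and 1.05), and without the member farthest from the median its 30 min median was -0.24, so its change of sign rests on the summary used. The same holds for glycolysis, with means of 0.0905 and 0.17, and for chaperones, with means of 1.08 and 0.38. Among the named genes, RNR1 differed by 3.84, CLB6 by 3.63, YDL159W-A by -3.16, EMI2 by -3.28 and the glycogen synthase gene GSY1 by -3.52. The 7 features at least 2-fold from 0 with opposite signs, chosen after their values were seen, were tL(UAG)J, tM(CAU)Q2, YER133W-A, YIL100C-A, YIR018C-A, YMR158W-B and YNL105W.

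Gene lists differed in how far their 60 min values lay from 0, given their 30 min values. One compression of all values on the 60 min array, with regression to the mean, was tested as the whole cause. If the noise of a list's members is independent, the values argue against it. The medians of 4 lists (G1/S, G2/M, cell wall and proteasome) lay nearer to or past 0 than lists matched on the 30 min value, beyond the spread over members, while 200 sets of lists drawn from the same matches gave at most 2, with members taken as independent. A dye bias that follows brightness stays open: lists of abundant transcripts deviated over a range of 0.89, but this rests on histones, the other lists spanned 0.141, and no brightness was measured. Unstressed RNA of another culture or growth state on one of the arrays and noise shared by the members of a list were not tested, and a change in the cells between 30 and 60 min stays open, since 1 array per time cannot separate it from a difference between cultures.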

How the results depend on the processing

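The alternative on natural logs was chosen after the data were seen, and the others before the data were examined. No paired analysis was possible because there is 1 array per time and the labels give no shared replicate numbers. Leaving out replicates was not possible either, and the number of arrays limits every value. Over 126 results, 538 alternative values were computed, of which 448 stayed within the limits set for each kind of value (1.5 times for a count, the resampling interval over members for a list median, which is wide for small lists), 83 moved, and 7 turned the sign of a list that stood apart from random lists. Some of the 448 could not have moved, since rescaling the 60 min array leaves every 30 min result as it was. Under rescaling 73 values stayed, these 30 min results included, 43 moved and 7 turned. Apart from turning all signs, 23 alternative values had the other sign, these 7 included. Where no construction is named, the cause was not tested. By construction, a lower threshold raises counts and a higher one lowers them. At 1.5-fold, 1826 features were positive and 1828 negative at 30 min, 984 and 945 at 60 min, and 1394 and 1270 for the difference, with 793 positive and 828 negative at both times and 35 opposite. At 3-fold these were 560 and 670, 179 and 41, 420 and 198, 154 and 25, and 0 opposite. With symbols alone, 280 features were positive at 60 min and 0 were opposite, with r = 0.81 and rho = 0.78. Turning the sign swaps 297 and 458 at 60 min. Read as natural logs, 806 were positive and 728 negative at 60 min, 1031 were negative for the difference, and 637, 636 and 24 were positive, negative and opposite at both times. Without the farthest 1% r was 0.75 and the covariance 0.547, without ribosomal protein and ribosome biogenesis genes rho was 0.753, and the covariance less the bound for a shared reference was 0.357. Means in place of medians gave 0.0905 for glycolysis at 30 min and 0.0781 for its difference, 0.38 for chaperones, 0.85 for fatty acid oxidation and -0.75 for sulphur genes at 60 min, and 0.75 for the ergosterol difference.

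Rescaling the 60 min array by 2.02, to the spread of the 30 min array, enlarges all its values by construction. The factor is the ratio of the median absolute deviations, 0.636 at 30 min and 0.315 at 60 min. Another measure of spread, such as the SD (1.33 and 0.71), would give another factor. Slight turns of sign may depend on this choice. Rescaling gave 1155 positive and 1188 negative features at 60 min, with 700, 787 and 28 positive, negative and opposite at both times. The list medians at 60 min became 6.86 for osmostress reporters, 2.28 for trehalose and glycogen, 1.23 for redox defence, 1.35 for hexose transporters, 0.89 for the tricarboxylic acid cycle, 0.57 for the respiratory chain, 1.35 for fatty acid oxidation, -1.35 for cytosolic and -0.19 for mitochondrial ribosomal proteins, -1.80 for ribosome biogenesis, -1.52 for RNA polymerases I and III, -0.999 for translation factors, -1.12 for tRNA synthetases, -0.81 for amino acid synthesis, -0.76 for sulphur genes, -0.60 for M/G1, -2.29 for histones, 0.76 for autophagy, -1.32 for pheromone response and 1.15 for meiosis. The sign of the difference turned for 15 lists. Of these, 7 stood apart from random lists before: osmostress reporters (1.495), glycerol metabolism (0.0235), redox defence (0.21), hexose transporters (0.27), fatty acid oxidation (0.00935), alpha-specific genes (-0.0171) and meiosis (0.22). The other 8 were cation transport (0.0164), the respiratory chain (0.0312), M/G1 (-0.19), the phosphate regulon (-0.51), pheromone response (-0.32), purine synthesis (-0.0511), HOG components (0.00282) and the marker loci (0.35). The differences that moved and kept their sign were -0.50 for trehalose and glycogen, -0.11 for the tricarboxylic acid cycle, 0.95 and -0.22 for cytosolic and mitochondrial ribosomal proteins, 1.53 for ribosome biogenesis, 0.97 for RNA polymerases, 0.23 for translation factors, 0.19 for tRNA synthetases, 0.34 for amino acid synthesis, -0.55 for sulphur genes, 1.15 for the cell wall, -1.41 for histones and -0.35 for autophagy.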

Other observations

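All tests in this part were chosen after the results were seen.

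Features of other classes were not placed among random sets, and their values are given as a description. Of 136 tRNA genes, 123 had negative values at 30 min and 113 at 60 min (medians -0.81 and -0.70, interquartile ranges -1.16 to -0.46 and -1.02 to -0.32). Of 68 snoRNA and snRNA genes, 51 and 63 were negative (medians -0.25 and -0.43). The 24 mitochondrially encoded features had a higher median at 60 min (0.66) than at 30 min (0.30), and 23 of them were above 0 at 60 min. The 582 reading frames absent from the reference table had medians of 0.37 and 0.29, against -0.05 and -0.02 for the 5262 measured features with a symbol.

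Ratios of neighbouring genes were correlated for some arrangements. For 40 overlapping pairs on the same strand, the correlation of ranks across pairs was 0.852 at 30 min and 0.892 at 60 min, so the value of an overlapping feature is not separate evidence. Without overlap, it was 0.171 at 30 min for 1513 divergent pairs (transcribed away from each other) and 0.131 for 2813 tandem pairs, and 0.103 and 0.1003 at 60 min. For 1499 convergent pairs it was 0.0415 at 30 min, inside the shuffled range of -0.0526 to 0.0471, and 0.0571 at 60 min, above the shuffled range of -0.0456 to 0.0511. Signal from the opposite strand would raise convergent pairs at least as much, but divergent exceeded convergent pairs by 0.130 at 30 min (95% resampling interval 0.0610 to 0.198). At 60 min the gap was 0.0461 and its interval, -0.0299 to 0.119, includes 0. Without pairs that hold a ribosomal gene or share a list, divergent pairs had 0.154 at 30 min, above the shuffled range, which argues against shared lists as the whole cause. What else neighbours share was not tested.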
